A study of Sus scrofa with 29 samples.

How the data were processed

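RNA from fibroblasts of Göttingen minipigs was measured by sequencing. Per the labels' protocols, messenger RNA was selected with oligo-dT and sequenced as single-end reads on a BGIseq-500 instrument. Per the submitters' processing notes, the tools named are HISAT2 2.1.0, HTSeq 0.9.1 and DESeq2 2.11.40.6, and the genome build is Sscrofa11.1. The deposited table holds TPM values, 1 column per sample, and how the authors made the TPM from the reads is not given in the sources used here. Read counts were not used here, so the depth per sample is unknown and no counting interval can be given. Low values are the least precise. The columns summed to between 589124 and 659747 TPM, below the fixed total that TPM of all transcripts has, so the table holds part of what the TPM were scaled over.

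Of the 29 columns of per-sample values, 2 were not used. They share 1 name, that of animal 606 with the γ inhibitor, and no column is named for animal 606 with the β inhibitor, so neither could be assigned. The 27 remaining columns were matched to samples by name. Samples with LY294002 and cells of a PS1-only genotype were not analysed here. WT animals were 498, 499 and 500 (line label Master F2, marked P5) and 512 (line label (A)RMCE F1) and 522 ((A)RMCE F1 far 3400), both marked P9 and grouped here as RMCE F1. APP/PS1 animals were 557 and 558 (so2709), 606 and 607 (so2603) and 550 (so2683), all marked P5. No 2 columns held identical values, and correlations between samples ran from 0.923 to 0.984. Replicates are separate animals, and each line label belongs to 1 genotype, so family and genotype cannot be separated.

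Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend and robust estimation), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Genes at 1 TPM or more in at least 4 of the 27 samples were tested, 10839 of 17589; 2204 genes were at 0 in every sample used. Among the tested rows 480 carry an Rfam family name. Symbols come from the table. Positions come from the NCBI RefSeq annotation of Sscrofa11.1 by unique symbol, which gave 9903 of the tested genes a position (91.4%).

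Genotypes were compared within each medium with those samples alone. Each inhibitor was compared with vehicle in a model of the 4 group means, as the mean of the genotypes, within each genotype and as the difference between genotypes, and the inhibitors were compared with each other likewise. The design and its alternatives were chosen before the data were examined, with no block in the main fit and the animal as replicate block as an alternative. Vehicle and inhibitor samples came from the same animals, except that 606 had a vehicle sample only and 550 had none with the β inhibitor. Fits without the block therefore compare partly different animals. Pairs with vehicle came from 8 animals for the β inhibitor and 9 for the γ inhibitor. The deviations of samples from their group means correlated at 0.188 to 0.674 (median 0.529) over the 25 pairs from 1 animal, against a median of −0.173 between animals, and 26 of 26 samples correlated best with a sample of their own animal. The animal numbers therefore pair the samples, and blocked values are given beside the others. With 3 to 5 animals per group, single values were also tested with two-sided exact permutation tests.

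Gene lists were tested with camera at a preset correlation of 0.01 and again with a correlation estimated for each list, adjusted over the lists in a comparison. Of 41 lists 37 had at least 4 measured members, and 846 of their 1004 genes were found in the table. Counts within a list are given over all genes and adjusted over the list alone.

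The genes named are APP and PSEN1, and in each main comparison the 8 with the largest rise and the 8 with the largest fall among genes past the threshold with a symbol and a mean of at least 5 TPM. Where fewer than 4 passed in a direction, those with the smallest p fill up to 4. The inhibitor comparisons add 8 and 8 from the blocked fit, each named list adds up to 4 members by smallest p, and each other comparison adds up to 3 and 3. Other genes are said to be chosen after their values were seen.

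Alternatives were a pseudocount of 0.1 or 5, no filter, median-ratio rescaling, quantile normalization, P5 samples alone, the replicate block, an estimated list correlation, split vehicle animals, and leaving out each animal in turn. The fits were tested on simulated data with 50 genes changed at each of 4 sizes among 10839. The changed genes were drawn from those averaging above about 5 TPM, so recovery of low genes was not examined. All sizes and a gene list were changed together, and genes were simulated independently with normal noise. Recovery with fewer changed genes or with correlated genes may differ. For genotype with vehicle 17 of 50 changed by 0.5 on the log2 scale were recovered, 37 of 50 by 1 and 47 of 50 by 2, with 12 false calls. For the β inhibitor as mean of genotypes 32 of 50 at 0.5 were recovered without the block and 45 with it. For the γ inhibitor these were 34 and 44.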

Results

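The series measured messenger RNA in skin fibroblasts grown from ear biopsies of Göttingen minipigs. Cells came from 5 wild-type (WT) animals and 5 animals carrying 2 human transgenes, called APP/PS1 here. One transgene encodes a short form of the amyloid precursor protein (APP) with the K670N and M671L changes, and the other encodes presenilin 1 with the M146I change. Presenilin 1 is the catalytic part of γ-secretase, which cuts APP after β-secretase has done so. Each culture was kept for 24 h with vehicle (DMSO), with 15 µM of β-secretase inhibitor IV, or with 2 µM of the γ-secretase inhibitor L-685,458. The 27 samples used were 5 WT samples in each medium, and 5, 3 and 4 APP/PS1 samples with vehicle, β inhibitor and γ inhibitor. Values were TPM, transcript abundances scaled for transcript length and depth, as deposited, so the read depth behind each value is unknown. The table summed to between 589124 and 659747 TPM per sample, and between 9990 and 10307 genes lay at 1 TPM or more.

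The transgene counterparts were examined first, with vehicle. PSEN1 (ENSSSCG00000002340, chromosome 7, 96478179 to 96567884 in Sscrofa11.1) rose from 29.4 ± 1.43 TPM in WT (SD, n = 5) to 60.4 ± 8.32 TPM in APP/PS1 (SD, n = 5). The log2 difference was 1.01 with an SE of 0.1 (limma, adjusted p = 0.00308). APP (ENSSSCG00000012022, chromosome 13, 189434854 to 189716120) averaged 194 ± 30.2 TPM in WT and 690 ± 342 TPM in APP/PS1. Its log2 difference was 1.67 with an SE of 0.337 and missed the limma threshold (adjusted p = 0.119). The lowest APP/PS1 animal, at 318 TPM, still lay above the highest WT animal, at 229 TPM (two-sided exact permutation p = 0.00794, the smallest that 252 regroupings can give). The spread of APP within APP/PS1 followed the line label. Animals 606 and 607, of line label so2603, averaged 334 TPM, while the other 3 APP/PS1 animals averaged 928 TPM. Reads of the human transgenes that align to the pig gene count in these values, and their share is unknown.

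**Figure D1:**
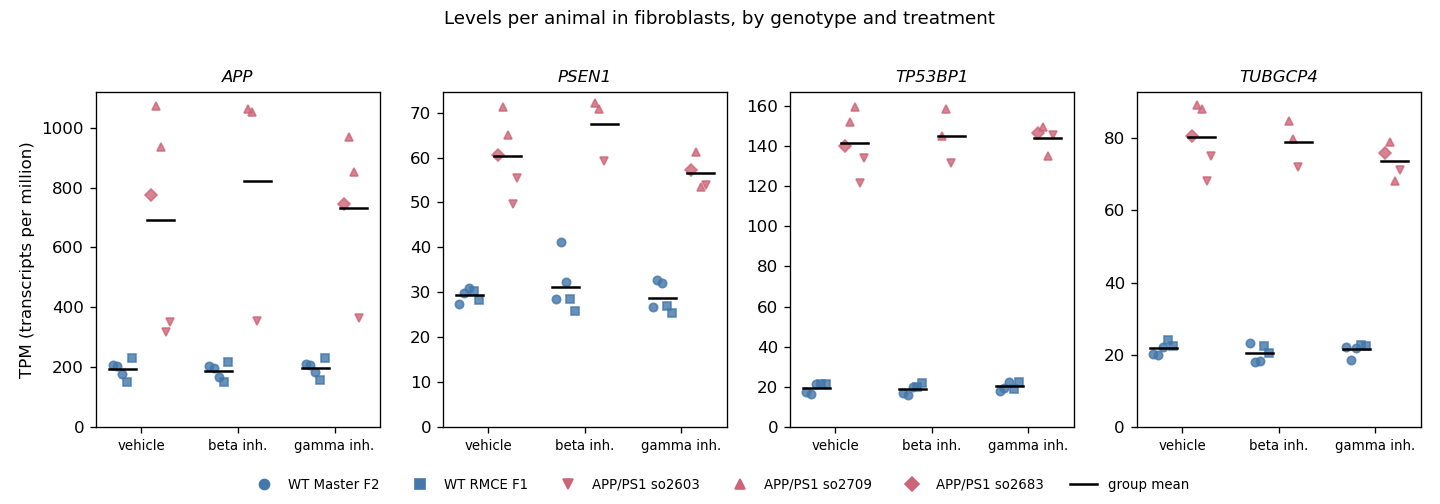
TPM of APP, PSEN1, TP53BP1 and TUBGCP4 (vertical axes) in each animal, by genotype and medium; markers show the line label and short lines the group means. With vehicle, TP53BP1 lies between 16.5 and 21.7 TPM in WT and between 122 and 160 TPM in APP/PS1.

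With vehicle, the largest genotype difference past the threshold on the log2(TPM + 1) scale was that of TP53BP1, a neighbour of TUBGCP4 on chromosome 1. TP53BP1, which encodes a DNA double-strand break repair protein, rose from 19.7 ± 2.47 to 142 ± 14.9 TPM with vehicle (SD, n = 5 each). The log2 difference was 2.79 with an SE of 0.108 (limma, adjusted p = 7.75e-07). TUBGCP4, a component of the γ-tubulin ring complex, rose from 21.8 ± 1.76 to 80.2 ± 8.86 TPM, a log2 difference of 1.83 with an SE of 0.0961 (adjusted p = 8.87e-06). ALDH1A3, an enzyme of retinoic acid synthesis 11.4 Mb away on the same chromosome (139451080 to 139491514), fell from 6.92 ± 1.94 to 0.942 ± 0.427 TPM (log2 difference −2.03, SE 0.205, adjusted p = 0.00308). These 3 genes and PSEN1 were the 4 genes called, 3 higher and 1 lower, where 1159 genes had an unadjusted p under 0.05 and 542 were expected by chance. The genes with the next smallest p in each direction were not past the threshold. CLGN, a testis chaperone gene, differed by 2.61 (adjusted p = 0.0859) and PCK2, a mitochondrial gluconeogenic enzyme, by −1.11 (adjusted p = 0.0635). MAPKAPK3 differed by −0.54 (adjusted p = 0.0804) and SPRED1 by −0.57 (adjusted p = 0.0859). The count of 4 became 10 without animal 500 or 557 and 21 without animal 606, where APP was past the threshold.

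TP53BP1 (ENSSSCG00000031949, 127958500 to 128032370) and TUBGCP4 (ENSSSCG00000004708, 128029393 to 128084039) overlap by 2978 bases. Whether reads were counted by strand is not given in the sources used here, so reads from the overlap cannot be assigned to either gene. MAP1A, PPIP5K1 and PDIA3, neighbours chosen after their values were seen, were not past the threshold with vehicle. MAP1A (127916639 to 127936952) differed by 0.80 (SE 0.155, adjusted p = 0.112), PPIP5K1 by 0.45 (SE 0.112, adjusted p = 0.185) and PDIA3 by 0.28 (SE 0.101, adjusted p = 0.355). The lowest APP/PS1 animal lay above the highest WT animal for MAP1A (49.7 against 40.0 TPM) and PPIP5K1 (4.82 against 4.35 TPM). The two-sided exact permutation p was 0.00794 for each, not adjusted over genes. On the other side of TUBGCP4, ADAL differed by −0.05 (SE 0.12). Over the 29 tested genes farther out, up to 2 Mb away, the median log2 difference was −0.04, with a range of −0.32 to 0.16.

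**Figure D2:**
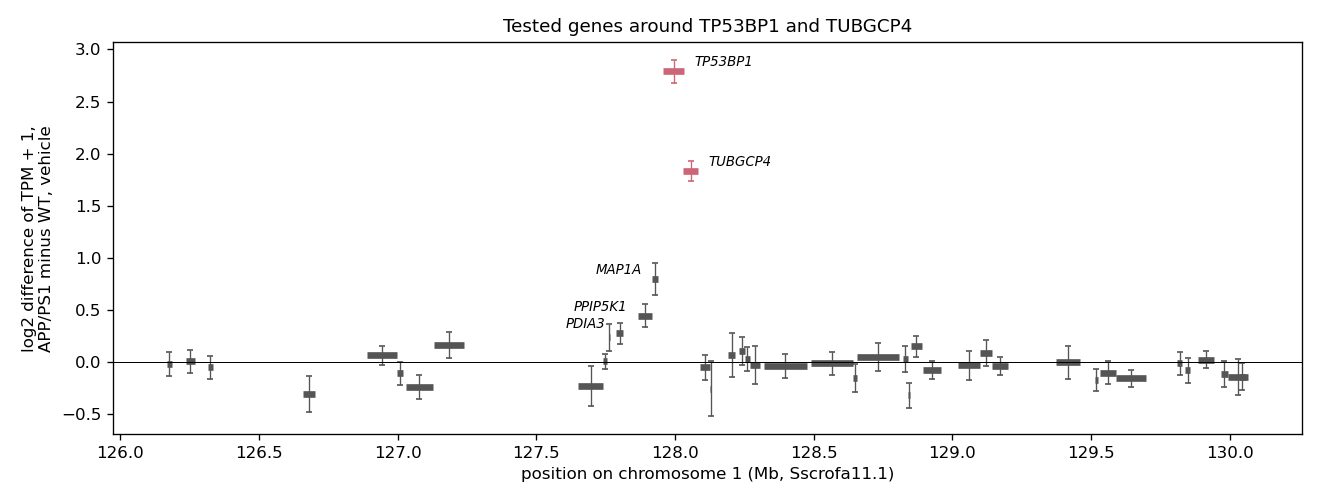
Log2 difference of TPM + 1 between APP/PS1 and WT with vehicle (vertical axis) for the tested genes around TP53BP1, by position on chromosome 1 in Mb (horizontal axis). Thick lines span each gene, error bars are 1 SE, and red marks genes past the threshold; TP53BP1 stands at 2.79, TUBGCP4 at 1.83 and MAP1A, not past it, at 0.80.

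Gene lists fixed before the data were examined were tested against all other genes in the same comparison. With vehicle, 25 of 29 measured targets of ATF4, the transcription factor of the integrated stress response, lay below 0 in APP/PS1, with a median log2 difference of −0.34 (camera, adjusted p = 2.00e-06). The list's call was lost with an estimated correlation (adjusted p = 0.32). No member passed over all genes, and 10 fell when adjusted over the list alone, among them PCK2, PHGDH (−0.88), SARS (−0.41) and TRIB3 (−0.85). PHGDH is the entry enzyme of serine synthesis. The 13 mitochondrially encoded genes all lay above 0, with a median of 0.28 (adjusted p = 9.00e-07, and adjusted p = 0.32 with an estimated correlation), and 0 passed over the list alone. Fibroblast markers were lower, 12 of 16 below 0 with a median of −0.53 (adjusted p = 9.19e-04, and adjusted p = 0.32 with an estimated correlation). Of these, 9 fell and 1 rose when adjusted over the list alone, and the matrix proteoglycans DCN (−1.90) and LUM (−1.66) were among the 9. The 16 measured HOX genes all lay below 0, with a median of −0.54 (adjusted p = 1.65e-04, and adjusted p = 0.562 with an estimated correlation). HOXB3 (−1.09), HOXB7 (−1.40) and HOXB2 (−0.51) fell when adjusted over the list alone. Cholesterol synthesis genes were higher, 20 of 25 above 0 with a median of 0.15 (adjusted p = 0.00144, and adjusted p = 0.32 with an estimated correlation). This difference followed the line label. Animals 550, 557 and 558 had list means of 4.978 to 5.028, above the WT range of 4.699 to 4.894. The so2603 animals 606 (4.638) and 607 (4.826) lay below and within that range. INSIG1, a sterol-regulated brake on SREBP processing, rose by 1.09 when adjusted over the list alone.

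All 42 measured cell cycle genes lay below 0 in APP/PS1, with a median of −0.30 (adjusted p = 4.59e-05, and adjusted p = 0.675 with an estimated correlation), and 0 passed over the list alone. Their mean log2 level followed the line label, at 5.48 in the WT animals of Master F2, 5.11 in those of RMCE F1, 5.55 in so2603, and 4.66 in both so2683 and so2709. The 33 ribosomal protein genes all lay below 0 as well, with a median of −0.16 (adjusted p = 1.65e-04, and adjusted p = 0.622 with an estimated correlation). That call was lost without animal 522 (adjusted p = 0.1). Of the 37 lists, 15 passed with the preset correlation and 0 with an estimated one. With P5 samples alone, which leaves out the 2 WT animals marked P9, 5 lists passed, fibroblast markers (adjusted p = 0.177), HOX genes (adjusted p = 0.43) and the APP processing list (adjusted p = 0.0852) were not past the threshold, and the ribosomal difference turned upward (adjusted p = 0.642).

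The genotype comparison was repeated within each inhibitor. TP53BP1 rose by 2.88 with the β inhibitor (adjusted p = 6.23e-05) and by 2.78 with the γ inhibitor (adjusted p = 4.88e-07), and TUBGCP4 rose by 1.90 and 1.73. ALDH1A3 fell by 2.24 and 2.32 (adjusted p = 0.0499 and 0.0028). Limma called 6 genes with the β inhibitor, 3 higher and 3 lower. SCD, the stearoyl-CoA desaturase, rose from 49.5 ± 3.06 TPM (SD, n = 5) to 98.6 ± 11.4 TPM (SD, n = 3), a log2 difference of 0.98 (SE 0.0987, adjusted p = 0.015). BCAR3, an adhesion signalling adaptor, fell by 3.23 (adjusted p = 0.00969) and COQ7, a coenzyme Q synthesis enzyme, fell by 2.03 (adjusted p = 0.00245). For the γ inhibitor 18 genes were called, 13 higher and 5 lower. APP rose by 1.80 (SE 0.266, adjusted p = 0.0418), PSEN1 by 0.96 (adjusted p = 0.00457), and MAP1A by 1.04 (adjusted p = 0.0223). LHFPL2 fell by 2.91 (SE 0.156, adjusted p = 2.77e-05) and PCOLCE2, an enhancer of procollagen processing, by 0.69 (adjusted p = 0.0289). Over the 3 media, 21 genes were called at least once and 3 in all 3 media, namely TP53BP1, TUBGCP4 and ALDH1A3. In all 3 media 20 of the 21 had the same sign. The media share animals, so these repeats are not independent of each other. Under the β inhibitor APP differed by 1.98 (adjusted p = 0.171) and PSEN1 by 1.10 (adjusted p = 0.114), which were not past the threshold. The count with the γ inhibitor was 67 without animal 607, 38 without 500, and 7 to 9 without 498, 499, 512, 550, 557 or 558; that with the β inhibitor was 3 without 498 and 14 without 607. The calls of APP and PCOLCE2 with the γ inhibitor and of ALDH1A3, SCD and BCAR3 with the β inhibitor were lost when some single animals were left out, and that of SCD also under median-ratio scaling and that of ALDH1A3 under each scaling, filter and pseudocount alternative.

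Gene lists also differed by genotype within the inhibitors. With the β inhibitor, 23 of 25 cholesterol synthesis genes lay above 0 in APP/PS1, with a median of 0.36 (camera, adjusted p = 3.63e-15, and adjusted p = 0.15 with an estimated correlation). Adjusted over the list alone 9 rose, among them SC5D (0.62), MSMO1 (0.68), FDFT1 (0.52) and SQLE (0.46). The mitochondrially encoded genes had a median of 0.39 (adjusted p = 1.61e-09, and adjusted p = 0.596 with an estimated correlation), and 7 of 13 rose over the list alone. With the γ inhibitor, 34 of 39 lysosome and autophagy genes lay above 0, with a median of 0.24 (adjusted p = 4.68e-06, and adjusted p = 0.713 with an estimated correlation). The ATF4 targets had a median of −0.44 (adjusted p = 3.86e-06, and adjusted p = 0.707 with an estimated correlation), and 12 fell and 1 rose over the list alone, with PSPH (−0.60), SLC7A11 (−0.82), MTHFD2 (−0.61) and ASNS (−0.92) among those that fell. Beside these differences, the cell cycle list lay lower in APP/PS1. Its median was −0.47 with the β inhibitor (camera, adjusted p = 2.53e-09, and adjusted p = 0.649 with an estimated correlation). With the γ inhibitor it was −0.55 (camera, adjusted p = 1.29e-10, and adjusted p = 0.713 with an estimated correlation). These sizes cannot be set against that with vehicle, where animal 606 also entered, at a list mean of 5.67. Animal 607, of the same line label, lay within the WT range. Its list mean was 5.215 with the β inhibitor (WT 4.981 to 5.669) and 5.382 with the γ inhibitor (WT 4.883 to 5.672).

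The β inhibitor was then compared with vehicle, as the mean over genotypes. In the fit with the animal as block, EGR1, an immediate early transcription factor, rose by 1.17 on the log2 scale (SE 0.172, adjusted p = 0.0337). STC1 (0.79), BHLHE40 (0.69), the matricellular gene CYR61 (0.65), MAFF (0.59), ACKR3 (0.56), CHST4 (0.54) and the hyaluronan-degrading CEMIP (0.54) rose with it, with adjusted p between 0.0173 and 0.0496. Genes that fell were NPNT (−0.44), CYP1B1 (−0.42), WASHC4 (−0.38), DSN1 (−0.32), WDHD1 (−0.32), BEX3 (−0.32), FAM111A (−0.30) and MRE11 (−0.29), with adjusted p between 0.0239 and 0.0431. DSN1 is a kinetochore component, WDHD1 a DNA replication factor and MRE11 a DNA repair nuclease. The blocked fit called 97 genes, 51 higher and 46 lower. Without the block, limma called 0 genes, and 237 had an unadjusted p under 0.05. In that fit the smallest p belonged to SCD (0.35), FOS (0.65), PGD (0.21) and EGR1 (1.20) among higher genes and to CDK14 (−1.63), DST (−1.22), SFSWAP (−0.25) and RECQL (−0.53) among lower ones, with adjusted p of 0.962 or more. With median-ratio scaling the blocked fit called 154, 115 higher and 39 lower. The blocked count was 0 with P5 samples alone and without animal 522 or 607, 1 without 558, 2 without 512, 4 without 500 or 557, and 42 without 498.

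Cholesterol synthesis genes, the targets of SREBP2, were higher with the β inhibitor, 25 of 25 above 0 with a median of 0.17 (camera, adjusted p = 5.09e-13, and adjusted p = 0.0457 with an estimated correlation). In the blocked fit the median was 0.12 (adjusted p = 5.84e-08, and adjusted p = 0.067 with an estimated correlation). There the LDL receptor gene LDLR rose by 0.28 (adjusted p = 0.0262), and 7 rose when adjusted over the list alone, with MVD (0.28), FDPS (0.17) and SREBF2 (0.30) among them. Fatty acid synthesis and LXR target genes were also higher, with 10 of 14 above 0 (adjusted p = 5.82e-05, and adjusted p = 0.0457 with an estimated correlation). In the blocked fit their estimated-correlation call was lost (adjusted p = 0.284 with an estimated correlation).

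Cell cycle genes were lower with the β inhibitor, 40 of 42 below 0 with a median of −0.24 (adjusted p = 5.64e-09, and adjusted p = 0.461 with an estimated correlation). Animals 606 and 550 enter that fit with vehicle only, at cell cycle means of 5.67 and 4.66. Within the 8 paired animals the list mean changed by −0.162 on average, and without 606 the call was kept (camera, adjusted p = 7.49e-05). In the blocked fit, 11 fell over all genes and 26 over the list alone, and KIF11 (−0.26), CENPF (−0.27), BUB1B (−0.28) and CENPE (−0.26), all mitotic genes, had the smallest p. ER chaperones were higher, 19 of 20 above 0 with a median of 0.15 (adjusted p = 5.64e-09, and adjusted p = 0.379 with an estimated correlation), and with the block PDIA4 rose by 0.19 (adjusted p = 0.0495). ATF4 targets were higher too, 27 of 29 above 0 with a median of 0.17 (adjusted p = 2.37e-06, and adjusted p = 0.379 with an estimated correlation). Of the inflammatory cytokine list 21 of 25 genes lay above 0 (adjusted p = 4.65e-04, and adjusted p = 0.466 with an estimated correlation), and IL11 (0.75) and PTGS2 (0.90) rose over the list alone with the block. Animal 499 decided that list's call, which was lost without it (adjusted p = 0.164). Its list mean rose by 2.35, against 0.01 to 0.25 in the other 7 animals. In total 16 lists passed with the preset correlation and 2 with an estimated one.

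**Figure D3:**
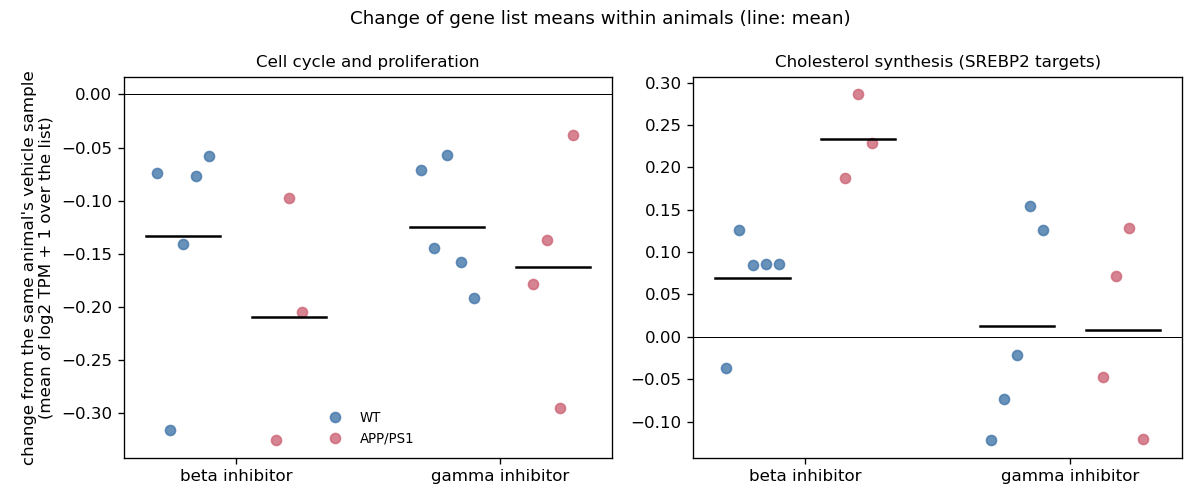
Change in the mean log2 level of the cell cycle list and the cholesterol synthesis list within each animal (vertical axes), for each inhibitor against vehicle, by genotype. Each point is 1 animal; the cell cycle mean was lower in 8 of 8 animals with the β inhibitor and in 9 of 9 with the γ inhibitor.

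Whether the β inhibitor response differed by genotype was tested as an interaction. Limma called 0 genes, and 70 had an unadjusted p under 0.05; with the block 0 were called and 370 had such a p. The cholesterol synthesis list differed, 23 of 25 genes having a larger response in APP/PS1, with a median difference of 0.22 (camera, adjusted p = 5.61e-14, and adjusted p = 0.0414 with an estimated correlation). The blocked fit gave a median of 0.20 (adjusted p = 1.78e-11, and adjusted p = 0.0236 with an estimated correlation). Per animal, the list mean changed by 0.23 ± 0.0496 in APP/PS1 (SD, n = 3) and by 0.07 ± 0.0622 in WT (SD, n = 5). All 3 APP/PS1 changes exceeded the 5 WT changes (two-sided exact permutation p = 0.0179, chosen after the values were seen). Within APP/PS1 alone 24 of 25 genes lay above 0 with a median of 0.28 (adjusted p = 5.00e-21, and adjusted p = 0.00706 with an estimated correlation). Beside it, the cell cycle list changed by −0.21 ± 0.114 in APP/PS1 and −0.13 ± 0.107 in WT (two-sided exact permutation p = 0.375). Within APP/PS1 limma called 0 genes, with 164 at an unadjusted p under 0.05. The block called 3, in which BHLHE40 (0.94) and SLITRK2 (0.83) rose and CYP1B1 (−0.69) fell, each with an adjusted p of 0.0354. Within WT 0 genes were called, with 104 at an unadjusted p under 0.05, and with the block 0 were called and 1131 had such a p.

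The γ inhibitor was compared with vehicle in the same way. In the blocked fit EGR1 rose by 1.64 (SE 0.179, adjusted p = 0.0147) and FOS, another immediate early gene, by 0.72 (adjusted p = 0.0272). ALDH3A1, an aldehyde dehydrogenase, rose by 1.10 (adjusted p = 0.024), from 7.20 ± 3.37 TPM (SD, n = 5) to 32.03 ± 17.9 TPM (SD, n = 4) in APP/PS1. In WT its levels were 3.35 ± 1.97 TPM with vehicle and 5.20 ± 3.03 TPM with the γ inhibitor (SD, n = 5 each). AKAP10 (0.77), DACT3 (0.77), FAM20A (0.76), the prostaglandin D synthase gene PTGDS (0.73) and SNED1 (0.70) also rose, with adjusted p between 0.0119 and 0.0467. AKAP10 was higher in 6 and lower in 3 of the 9 paired animals. In WT it averaged 10.82 ± 5.34 TPM with vehicle and 11.93 ± 3.85 TPM with the γ inhibitor (SD, n = 5 each), while it rose by 1.34 within APP/PS1. All genes that fell were NIPAL1 (−0.45), the hexokinase HK2 (−0.44), NABP1 (−0.39), the collagen prolyl hydroxylase P4HA1 (−0.36), GDF11 (−0.33), TIPARP (−0.32) and ODC1 (−0.27), the entry enzyme of polyamine synthesis. The blocked fit called 50 genes, 43 higher and 7 lower. Without the block limma called 0, and 850 had an unadjusted p under 0.05. In that fit the smallest p belonged to FOS (0.74), EGR1 (1.68), SIRT2 (0.43) and DACT3 (0.76), and to GDF11 (−0.34), SEC23IP (−0.20), CLDND1 (−0.26) and INTS2 (−0.31), with adjusted p between 0.191 and 0.621. The blocked count was 0 without animal 550 or 557, 7 without 558, 84 without 607, between 19 and 33 without any single WT animal, and 18 with P5 samples alone.

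Cell cycle genes were lower with the γ inhibitor as well, 38 of 42 below 0 with a median of −0.26 (camera, adjusted p = 1.82e-06, and adjusted p = 0.748 with an estimated correlation). Animal 606 enters that fit with vehicle only, and its cell cycle mean of 5.67 was the highest of the APP/PS1 vehicle samples. Part of the difference therefore reflects which animals lack a partner. Within the 9 paired animals the list mean changed by −0.141 on average, and without 606 the call was kept (camera, adjusted p = 0.00176). Adjusted over the list alone with the block 18 fell and 1 rose, and ANLN (−0.32), NUSAP1 (−0.27), CCNB2 (−0.31) and CCNB1 (−0.33) had the smallest p. Lysosome and autophagy genes were higher, 33 of 39 above 0 with a median of 0.12 (adjusted p = 2.48e-05, and adjusted p = 0.612 with an estimated correlation), and SQSTM1 (0.34), NPC2 (0.24), CTSB (0.28) and GPNMB (0.57) rose over the list alone with the block. Fibrillar collagen and matrix genes were higher, 33 of 38 above 0 with a median of 0.18 (adjusted p = 0.0141, and adjusted p = 0.612 with an estimated correlation), a call lost without animal 606 (adjusted p = 0.12). With the block elastin, ELN, rose by 0.59 (adjusted p = 0.0447), and 13 rose and 2 fell over the list alone. All 16 fibroblast markers lay above 0 with the block, with a median of 0.18 (adjusted p = 7.97e-05, and adjusted p = 0.0696 with an estimated correlation), and COL3A1 (0.28), VIM (0.20), DCN (0.24) and PDGFRB (0.34) rose over the list alone. The blocked call was kept without each of the 9 animals (adjusted p up to 3.16e-04), while that without the block was lost without animal 499 (adjusted p = 0.0529), 500 (adjusted p = 0.0544) or 606 (adjusted p = 0.0714). MHC class I presentation genes were higher, 8 of 9 above 0 (adjusted p = 8.27e-04, and adjusted p = 0.612 with an estimated correlation). The 13 mitochondrially encoded genes all lay below 0, with a median of −0.15 (adjusted p = 7.59e-04, and adjusted p = 0.612 with an estimated correlation). ER chaperones were lower, 17 of 20 below 0 (adjusted p = 0.00944, and adjusted p = 0.69 with an estimated correlation), and HSPA5 (−0.37) fell over the list alone with the block. Notch is another γ-secretase substrate. The list of Notch pathway genes, 14 of 18 above 0 with a median of 0.09, was not past the threshold (adjusted p = 0.0914).

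By genotype, the γ inhibitor response within APP/PS1 gave 0 genes in limma without the block, with 917 at an unadjusted p under 0.05, and 53 with it, 48 higher and 5 lower. EGR1 (1.87), ALDH3A1 (1.69) and AKAP10 (1.34) rose, and NIPAL1 (−0.63), TIPARP (−0.45) and ODC1 (−0.36) fell, in the blocked fit. That count was 0 without animal 557 or 558, 1 without 550, 11 without 498, 30 without 500 and 84 without 512. It was 1224 with P5 samples alone, which leaves out WT animals only, and these included all 53. In this fit WT animals enter only through the shared estimate of the spread. Leaving them out changes the count but not the APP/PS1 fold changes. Within WT 0 genes were called with or without the block, with 455 and 92 at an unadjusted p under 0.05. Set against each other with the block, the P9 animals 512 and 522 and the 3 P5 animals of WT differed in response at 2175 genes, 1573 higher and 602 lower in P9. This comparison was picked because the same split of the 5 animals had stood out, and the 10 ways to choose 2 of 5 animals cannot give a share under 0.05, so it shows no difference by P mark beyond these animals. Within either mark alone 0 were called, with 1419 (P5) and 3412 (P9) at an unadjusted p under 0.05. In WT as a whole, with the block, all 16 fibroblast markers lay above 0 with a median of 0.12 (camera, adjusted p = 6.66e-07, and adjusted p = 0.0219 with an estimated correlation). That call was lost with P5 samples alone (adjusted p = 0.112). Without the block the list's call was lost with P5 samples alone (adjusted p = 0.631) and without animal 498 (adjusted p = 0.0667), 499 (adjusted p = 0.0676), 500 (adjusted p = 0.0834) or 512 (adjusted p = 0.0635). The interaction called 0 genes in limma, with 133 at an unadjusted p under 0.05, and with the block 0, with 602 at such a p. Of the interferon-stimulated genes 25 of 27 had a higher response in APP/PS1, with a median difference of 0.56 (camera, adjusted p = 1.21e-09, and adjusted p = 0.695 with an estimated correlation). That call was lost with P5 samples alone (adjusted p = 0.174) and kept without animal 522 (adjusted p = 0.0019), a WT animal marked P9 whose list mean changed by −1.05 with the γ inhibitor, against −0.18 to 0.60 in the other 8 animals. Lysosome and autophagy genes had a median difference of 0.21 (adjusted p = 1.50e-07, and adjusted p = 0.695 with an estimated correlation). Of the NRF2 oxidative stress targets 16 of 18 had a higher response in APP/PS1, with a median difference of 0.24 (adjusted p = 2.30e-04, and adjusted p = 0.0408 with an estimated correlation); with the block the second call was lost (adjusted p = 0.552 with an estimated correlation).

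The inhibitors, which block consecutive cuts of APP, were also compared with each other, at different doses (15 µM and 2 µM), in 8 samples with the β and 9 with the γ inhibitor. With the block the difference rests on the 8 animals that had both. With the block 582 genes were called, 247 higher and 335 lower with the β inhibitor. STC1 (1.54), the nuclear receptor NR4A1 (1.25) and the cytokine IL11 (1.11) were higher, and CDK14 (−1.64), ALDH3A1 (−1.16) and SNED1 (−0.89) were lower, with adjusted p between 0.00483 and 0.0325. Without the block limma called 0, and 769 had an unadjusted p under 0.05. ER chaperones were higher with the β inhibitor, 19 of 20 above 0 with a median of 0.23 (camera, adjusted p = 4.44e-12, and adjusted p = 0.535 with an estimated correlation). With the block 6 rose, and 18 over the list alone, among them EDEM1 (0.22), PDIA4 (0.26), HYOU1 (0.46) and CALR (0.30). Glycolysis and hypoxia genes were higher (median 0.22, adjusted p = 3.86e-07, and adjusted p = 0.544 with an estimated correlation), and with the block 5 rose, including P4HA1 (0.46), PGK1 (0.31), HK2 (0.73) and PGAM1 (0.26). Cholesterol synthesis genes were higher (median 0.13, adjusted p = 1.53e-07, and adjusted p = 0.535 with an estimated correlation), and with the block HMGCS1 (0.36), MSMO1 (0.29), HMGCR (0.25) and STARD4 (0.29) rose. Fibroblast markers were lower (median −0.23, adjusted p = 0.0319, and adjusted p = 0.757 with an estimated correlation), a call lost without animal 499 (adjusted p = 0.0673) or 607 (adjusted p = 0.12), and with the block VIM (−0.27), PDGFRA (−0.36), COL3A1 (−0.45) and DCN (−0.42) were among the 6 that fell. The blocked count was 60 without animal 557, 110 without 558, 233 without 498, 256 without 522, 307 without 512, 328 without 500 and 104 with P5 samples alone.

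Both inhibitors were set against the same vehicle samples, so their fold changes share chance values. Across genes, which are not independent replicates, the correlation of the fold changes was 0.377. Unchanged groups simulated against the same vehicle samples gave 0.465 (0.402 to 0.522). With the block it was 0.407 against 0.46 (0.385 to 0.526). The covariance was 0.0112, above the simulated 0.00825 (0.00674 to 0.0103), and with the block 0.0126, above 0.00787 (0.00614 to 0.0103). The sign was the same for 64.1% of genes against 65.7% simulated (64.3 to 66.7), and with the block for 68.1% against 65.3% (63.9 to 66.1). Genes were simulated independently of each other, which leaves out any correlation between genes, so these ranges may be too narrow. A value outside them does not show a shared response. With the vehicle animals split between the inhibitors the median correlation was −0.0982 (−0.36 to 0.205 over 200 splits), and with the animals split between them 0.056 (−0.119 to 0.241 over 60 splits), ranges that include 0. Of the blocked calls, 1 gene, EGR1, rose with both inhibitors, of 51 and 43, where independent lists would share 0.202. Of the 46 and 7 genes that fell, 0 were shared, against 0.0297 for independent lists. The simulated groups gave at most 1 call, so they offer no reference for this overlap, and part of it may come from the shared vehicle samples.

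The lists of Alzheimer's disease risk genes and of reported targets of the APP intracellular domain were not past the threshold in any of the 12 comparisons without the block or of the 9 with it. Of the 55 measured risk genes 23 lay above 0 between genotypes with vehicle (camera, adjusted p = 0.526); PSEN1 rose over all genes, and over the list alone APP and ANKH (1.13) also rose and EPDR1 (−1.41) fell. The risk list's adjusted p was 0.079 with the β inhibitor, and with the block FOXF1 (0.40) and ADAMTS1 (0.51) rose. For the γ inhibitor it was 0.095, and CTSB (0.28) and APOE (0.45) rose over the list alone with the block. Of the 21 measured genes reported as targets of the APP intracellular domain, which γ-secretase releases, APP rose and TP53 (−0.56) fell over the list alone between genotypes with vehicle (adjusted p = 0.395). The list's adjusted p was 0.0735 with the β inhibitor and 0.354 with the γ inhibitor. Within animals its mean was higher with the β than with the γ inhibitor in 8 of 8, by 0.09 (0.03 to 0.17). This missed the threshold after adjustment over the lists (two-sided exact sign-flip permutation p = 0.00781, the smallest that 8 animals can give, adjusted 0.0721). The APP processing list was higher between genotypes with vehicle, 14 of 20 above 0 (camera, adjusted p = 0.00424, adjusted p = 0.0852 with P5 samples alone, and adjusted p = 0.32 with an estimated correlation). PSEN1 was the member that rose over all genes, and APP also rose over the list alone. Both are counterparts of the transgenes, so their rise follows from the genotype and the call is partly built in. The list was not tested without them. APP is also on the risk and target lists, and PSEN1 on the risk list.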

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

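The tests of the pattern on chromosome 1, the test for WT cells in cultures 606 and 607, the per-animal list tests and the counts of splits were chosen after the results were seen, as were splits with the block and list tests without each animal, and the comparison of responses by P mark.

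TP53BP1 and TUBGCP4 were higher in APP/PS1, with MAP1A beside them. A scaling of whole libraries is argued against, since the median log2 difference of all genes was −0.038. TPM are already scaled per sample, however, which limits how far that median could move. Whether an effect reaches further along the segment stays open: 18.7% of sets of as many neighbouring genes had a mean as high as the 11 other tested genes within 200 kb, yet 2 of the 11, PPIP5K1 and PDIA3, were higher at an unadjusted p under 0.05. A local effect of an inserted transgene, limited to the 3 genes or extending to one side, may be a candidate explanation, but the 3 were picked for the pattern, and the next gene, PPIP5K1, was at 0.446. Inherited sequence differences between families cannot be told apart from it, although WT animals marked P5 and P9 differed in TP53BP1 by a share of 0.0785 of the genotype difference, because each line label belongs to 1 genotype and no insertion site is given in the labels.

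APP was lower in APP/PS1 animals 606 and 607 than in the other 3, by 1.46 on the log2 scale with vehicle, where 2 against 3 animals cannot give an exact p under 0.1. Scaling is argued against by a median of 0.0897 over all genes between these animals, although the scaling of TPM per sample limits how far that median could move. WT cells mixed into the cultures would lower PSEN1 and TP53BP1 alike, but their excess over WT was at least 0.641 of that in the others, against 0.191 for APP. Fewer active copies of the APP transgene may account for the 0.191 and stays open, since copy number was not analysed here.

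Cholesterol synthesis genes were higher with the β inhibitor. Slower cell division alone is argued against by a narrow margin: within animals the list was higher with the β than with the γ inhibitor in 6 of 8 (two-sided exact sign-flip permutation p = 0.0469, 0.133 adjusted over 37 lists), while the cell cycle list differed by −0.0252 (exact p = 0.633), which does not show equality. A single animal is argued against for the call with the preset correlation, whose adjusted p was at most 4.49e-10 without each animal (camera, no block). With an estimated correlation the highest unadjusted p was 0.006 over leaving out each. That value was not adjusted over the lists, so it does not show that the adjusted call with an estimated correlation was kept. Solvent or toxicity at 15 µM stays open, because the volumes are not given in the labels; the mean change within animals was 0.131. A response to the inhibitor itself or to another target of it was not tested.

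Other splits of the samples were compared with the real one. Between genotypes with vehicle, 2 of 100 splits, the real one included, gave as many genes as the real 4. That share is under 0.05, but it was not adjusted over the comparisons and was chosen after the results were seen. It does not exclude chance. Of the other splits 23 gave at least 1 gene, and a split of 512, 522, 550, 557 and 558 from the rest gave 792. That split holds 3 APP/PS1 animals and both WT animals marked P9; 711 genes were lower there, 24 of them cell cycle genes (list median −0.62). With the γ inhibitor, 3 of 100 gave as many as the real 18, and 498, 499, 500 and 607 against the rest gave 518 (cell cycle median 0.78). These counts point to a structure of the samples other than genotype. With the β inhibitor, 3 of 56 gave as many as the real 6 (highest other 10), so chance cannot be excluded.

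For comparisons within animals, splits swapped the media within animals. With the block, the share of splits as large, the real one included, was under 0.05 for the β inhibitor (1 of 100, real 97, highest other 2), for the γ inhibitor (2 of 100, real 50, highest other 690) and between inhibitors (1 of 100, real 582, highest other 36). The real count was thus the largest of the splits drawn for the β inhibitor and between inhibitors, but not for the γ inhibitor. These shares were not adjusted over the comparisons, so they do not exclude chance. Leaving out 522 or 607 took the 97 to 0, and leaving out 550 or 557 took the 50 to 0. The 690 came from swapping 512, 522, 557, 558 and 607 (254 higher, 436 lower, cell cycle median 0.11). The 801 in the interaction came from taking 512, 522, 558 and 607 as APP/PS1, and the 531 within WT from swapping 512 and 522, the animals marked P9 (55 higher, 476 lower). These counts point to a structure of the samples. The split of 512 and 522 from the other WT animals, tested as a difference in response with the block, called 2175 genes for the γ inhibitor (at most 4 for any other 2 of the 5) and 2 for the β inhibitor. That test restates the split that prompted it and is no separate evidence, and 10 choices of 2 animals cannot give a share under 0.05. P mark and line label coincide in WT, so these cannot be told apart. Where 0 genes were called every split is as large by construction, so these counts say nothing about chance: 100 of 100 for the β inhibitor (highest other 2), the γ inhibitor (1), the γ interaction (1, and 801 with the block) and between inhibitors (2) without the block, and 56 of 56 for the β interaction (1, and 2 with the block). Within WT 16 splits, and within APP/PS1 4 with the β and 8 with the γ inhibitor, are too few for a share under 0.05. Within WT the real counts were 0, so 16 of 16 were as large by construction (highest other 1, and 2 with the block, for the β inhibitor; 0, and 531 with the block, for the γ inhibitor). Within APP/PS1, 4 of 4 and 8 of 8 were likewise without the block (real 0 each, highest other 1 and 0). With the block 1 of 4 (real 3, highest other 1) and 1 of 8 (real 53, highest other 1) were.

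A sample far from the others of its group was found in 12 of 280 groups over 56 named genes, where chance gives 14. The value is the gap to the nearest sample over the range of the group. Animal 607 with the γ inhibitor was highest in BCAR3 (0.953, at 14.8 TPM against 0.453 to 0.624), WDHD1 (0.836), AKAP10 (0.943) and ODC1 (0.865). Animal 606 with vehicle was highest in LHFPL2 (0.812, at 8.84 TPM against 0.79 to 1.46) and AKAP10 (0.886). Animal 557 with vehicle was highest in BHLHE40 (0.774) and lowest in NPNT (0.749). Animal 500 with vehicle was lowest in BCAR3 (0.754, at 0.918 TPM against 12.3 to 24) and highest in SFSWAP (0.734). TUBGCP4 was lowest in 499 with the γ inhibitor (0.801, at 18.5 TPM), and GDF11 in 522 with vehicle (0.841).

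Lists whose response differed between genotypes, by camera on the interaction with adjusted p as the value, were found for both inhibitors. With the β inhibitor these were cholesterol synthesis (5.61e-14), ribosomal proteins (3.13e-05), mitochondrially encoded genes (5.23e-05), fatty acid synthesis (1.17e-04), ATF4 targets (0.00107), oxidative phosphorylation (0.00107), cell cycle (0.0045), interferon-stimulated genes (0.0045), contractile and TGF-β genes (0.00479) and glycolysis (0.038). With an estimated correlation cholesterol (adjusted p = 0.0414) and fatty acid synthesis (adjusted p = 0.0459) passed, and the others were at adjusted p = 0.855. With the block as well, cholesterol (adjusted p = 0.0236) and ribosomal proteins (adjusted p = 0.0475) passed with an estimated correlation and fatty acid synthesis did not (adjusted p = 0.29). With the γ inhibitor these were interferon-stimulated genes (1.21e-09), lysosome (1.50e-07), cell cycle (3.98e-05), NRF2 targets (2.30e-04), MHC class I (0.00211) and ER chaperones (0.00471). Of these NRF2 targets passed with an estimated correlation (adjusted p = 0.0408), a call lost with the block (adjusted p = 0.552). With the block the interaction calls of interferon-stimulated genes (adjusted p = 0.179) and glycolysis (adjusted p = 0.1) with the β inhibitor, and of cell cycle genes (adjusted p = 0.0789) with the γ inhibitor, were lost. With P5 samples alone the calls of ATF4 targets (adjusted p = 0.331), cell cycle (0.0934), interferon-stimulated genes (0.646, reversed) and glycolysis (0.276) with the β inhibitor, and of interferon-stimulated genes (0.174) and MHC class I (0.156) with the γ inhibitor, were lost. Single animals also ended calls. With the β inhibitor these were ATF4 targets (0.959 without 557, reversed), mitochondrially encoded genes (0.141 without 557), oxidative phosphorylation (0.128 without 606), cell cycle (0.992 without 606, reversed, 0.176 without 557, 0.0521 without 558), interferon-stimulated genes (0.902 without 522, reversed, 0.0963 without 500, 0.232 without 558, 0.149 without 606), contractile genes (0.0722 without 499, 0.158 without 606, 0.0554 without 607) and glycolysis (0.0609 to 0.518 without 498, 512, 522, 557 or 606). With the γ inhibitor they were cell cycle (0.32 without 606), MHC class I (0.0578 without 606) and ER chaperones (0.179 without 557, 0.0765 without 558).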

How the results depend on the processing

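The no-filter, rescaling, quantile, pseudocount, P5 and leave-one-out values of the blocked fits, the list tests without each animal, the WT counts by P mark with the block, the block with an estimated correlation, and the correlation with animals split between inhibitors, were chosen after seeing the data; the other alternatives were planned. Of 1298 alternatives for 86 named genes, 943 kept direction and side of the threshold, 339 lost the threshold, 16 gained it and 0 reversed. Of 1926 for 137 list results, 1585 kept both, 329 lost the threshold and 12 reversed; of 259 counts, 195 stayed within 1.5 times. The cause of each change below was not tested, except that P5 alone and leaving out an animal use fewer samples. In blocked fits within a genotype, leaving out animals of the other genotype changes only the estimate of the spread, not the fold changes. Depth is unknown, so its limit cannot be stated.

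With the replicate block, genes called moved from 0 to 97 (β inhibitor, mean), 3 (β inhibitor, APP/PS1), 50 (γ inhibitor, mean), 53 (γ inhibitor, APP/PS1) and 582 (β against γ); lists moved to 11 (β inhibitor, WT) and 14 (γ inhibitor, WT), and mitochondrially encoded genes reversed for the β inhibitor in APP/PS1 (adjusted p = 0.941). The pairing changed no other count of genes. With P5 samples alone, counts were 9 (genotype, vehicle), 1 (β inhibitor, WT), and with the block 0 (β inhibitor, mean), 18 (γ inhibitor, mean), 1224 (γ inhibitor, APP/PS1) and 104 (β against γ). Lists passing were then 5 (genotype, vehicle), 9 (genotype, β inhibitor) and 0 (γ inhibitor, WT). Reversed were ribosomal proteins between genotypes with vehicle (adjusted p = 0.642) and γ inhibitor (0.278), interferon-stimulated genes in the β interaction (0.646) and with the γ inhibitor in WT (0.631), and mitochondrially encoded genes with the γ inhibitor in WT (0.679). With the block, the WT samples marked P9 alone gave 6 genes for the β and 0 for the γ inhibitor, and the P5 samples alone gave 0 for each. With no filter the blocked counts were 44 (β inhibitor, mean) and 360 (β against γ). With median-ratio scaling the blocked β inhibitor count was 154 (115 higher, 39 lower), and 3 lists passed for each inhibitor in WT.

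With an estimated correlation and no block, lists passing were 0 in each genotype comparison, 2 for the β inhibitor (mean), 0 in WT, 2 in APP/PS1 and 2 in its interaction, 0 for the γ inhibitor in mean, WT and APP/PS1, 1 in its interaction and 0 between inhibitors. With an estimated correlation and the replicate block, they were 0 (β inhibitor, mean and WT), 1 (β inhibitor, APP/PS1), 2 (its interaction), 1 (γ inhibitor, WT) and 0 (γ inhibitor, mean, APP/PS1 and interaction, and between inhibitors). The correlation of β and γ fold changes had a median of −0.0982 with vehicle animals split (−0.36 to 0.205) and 0.056 with animals split between inhibitors (−0.119 to 0.241), so neither has a clear sign.

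Leaving out each animal gave 4 to 21 genes for genotype with vehicle (21 without 606, 10 without 500 or 557), 3 (without 498) to 14 (without 607) with the β inhibitor, and 7 to 67 with the γ inhibitor (67 without 607, 38 without 500, 7 without 498, 550 or 557, 8 without 558, 9 without 499 or 512). Counts without the block were 0 to 1 for the β inhibitor (mean, WT, APP/PS1 and interaction) and the γ inhibitor (mean and APP/PS1), 0 for the γ inhibitor in WT and its interaction, and 0 to 2 between inhibitors. With the block they were 0 to 112 for the β inhibitor (0 without 522 or 607, 1 without 558, 2 without 512, 4 without 500 or 557, 42 without 498), 0 to 84 for the γ inhibitor (0 without 550 or 557, 7 without 558, 84 without 607, 19 to 33 without any WT animal), 0 to 84 in APP/PS1 (0 without 557 or 558, 1 without 550, 11 without 498, 30 without 500, 84 without 512) and 60 to 611 between inhibitors (60 without 557, 110 without 558, 233 without 498, 256 without 522, 307 without 512, 328 without 500).

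For list tests without each animal, the adjusted p of the results that reversed ran from 0.00505 to 0.864 (interferon-stimulated genes between genotypes with vehicle, reversed without 522), 9.00e-06 to 0.905 (ER chaperones between genotypes with the β inhibitor, reversed without 557), 2.88e-09 to 0.902 (interferon-stimulated genes in the β interaction, without 522), 1.78e-08 to 0.959 (ATF4 targets in the β interaction, without 557), 7.78e-08 to 0.992 (cell cycle in the β interaction, without 606) and 6.18e-06 to 0.634 (interferon-stimulated genes with the γ inhibitor in WT, without 522).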

Other observations

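The within-animal list tests here were chosen after the data were seen, with adjustment over 37 lists. The cell cycle list mean was lower in 8 of 8 animals with the β inhibitor, by −0.162 on average (two-sided exact sign-flip permutation p = 0.00781, adjusted 0.0413). In 9 of 9 it was lower with the γ inhibitor, by −0.141 (exact p = 0.00391, adjusted 0.0362). Fibroblast markers (0.164) and fibrillar collagen and matrix genes (0.155) were higher in 9 of 9 animals with the γ inhibitor (adjusted exact p = 0.0362 each), and heat shock genes were lower in 9 of 9 (−0.0693). Pericyte and smooth muscle markers were higher in 8 of 9 by a larger mean (0.196), not past the threshold (adjusted exact p = 0.0618). ER chaperones were higher in 8 of 8 animals with the β inhibitor (0.171, adjusted exact p = 0.0413), as were metalloproteinases and their inhibitors (0.148), p53 targets (0.0688) and inflammatory cytokines (0.406), while oxidative phosphorylation genes (−0.0536) and protocadherins (−0.0941) were lower in 8 of 8, each at the same adjusted p. The cytokine changes ran from 0.0113 to 2.35, the highest in animal 499, and averaged 0.127 in the other 7. ER chaperones differed between inhibitors in 8 of 8 (0.279, adjusted exact p = 0.0721, not past the threshold). Their unadjusted exact p was 0.00781 here and against vehicle, the smallest that 8 animals can give, so the 2 adjusted values differ only through the other lists. The cholesterol list was higher in 7 of 8 animals with the β inhibitor but missed the threshold after adjustment (0.131, exact p = 0.0156, adjusted 0.0641), and with the γ inhibitor it was higher in 4 of 9 (0.0106, exact p = 0.758).

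Lists of matrix metalloproteinases and their inhibitors, and of basement membrane genes, were fixed with the others. With the β inhibitor 16 of 17 metalloproteinase genes lay above 0 (camera, adjusted p = 0.00107, and adjusted p = 0.379 with an estimated correlation), and with the block PLAUR (0.35) and ADAMTS1 (0.51) rose. With the γ inhibitor and the block 10 of 12 basement membrane genes lay above 0 (adjusted p = 0.00849, and adjusted p = 0.425 with an estimated correlation), and COL18A1 (0.35) rose over the list alone. All 8 measured pericyte and smooth muscle markers lay above 0 there (adjusted p = 0.00477, and adjusted p = 0.425 with an estimated correlation), with CSPG4 (0.48) past the threshold over all genes.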
